A study of Homo sapiens with 16 samples.

How the data were processed

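Polyadenylated RNA of H9 embryonic stem cells, which carry EGFP at the REX1 promoter, was sequenced after transfection of pooled siRNAs in 6 groups: Luciferase and Control (n = 2 each) and SALL4, VRTN, DSCC1 and SEPHS1 (n = 3 each). Per the submitters' processing notes, the cells grew on Matrigel in mTeSR1 medium and received 30 to 50 nM siRNA. Those against SALL4, DSCC1, SEPHS1 and luciferase were made by enzymatic digestion, and those against VRTN were synthetic. Libraries were made with a Lexogen SENSE kit and read as 80 bp single ends on an Illumina NextSeq. Harvest was at 48 h for SALL4 and VRTN and at 72 h for DSCC1 and SEPHS1, per the labels, which give no time for the controls. The protocol text gives a longer growth period than the sample labels do, and the labels were used here.

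The deposited table holds raw gene counts, which per the labels the authors made by aligning reads to GRCh38 with STAR 2.4.0.1 and counting them with HTSeq 0.9.1. The table was checked to hold whole numbers for 60675 Ensembl identifiers in 16 libraries, 33486 of them without a count in any library. How reads shared between gene copies were treated, the strand setting and the annotation release are not stated. Of the identifiers, 56558 were named from a gene name table, 497 from GENCODE release 29, which also gave positions, and 3620 stayed unnamed. Library totals ran from 18597262 to 28662389 counts. Reads carry no molecular identifiers, so floors of 3 counts, 0.105 to 0.161 CPM of the library totals before TMM scaling, cover counting error only.

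Genes were filtered with filterByExpr, which kept 19772 and left out 40903. Normalisation was TMM and the test was edgeR 4.0.16's quasi-likelihood test in R 4.3.3, over 1 design with 6 groups, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold for a call. The common dispersion was 0.347. Each knockdown was set against the mean of the Luciferase and Control groups, and 3 further contrasts compared SALL4 with VRTN, DSCC1 with SEPHS1 and Control with Luciferase. The SE is the absolute log2 fold change divided by the square root of the F statistic. Gene groups were 43 fixed lists with 934 distinct genes, written before the data were examined, as were the contrasts, tests, thresholds, the rule for named genes and the alternatives not called added. Of the lists, 42 had the 5 tested members needed for camera from limma 3.58.1, two-sided, with a preset correlation of 0.01 between genes. Each was tested again with an estimated correlation and with fry.

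Genes are named by a fixed rule. It takes the 4 targeted genes, then the 6 genes with the largest rises and the 6 with the largest falls among called genes that average at least 2 log2 CPM, carry a gene symbol and have knockdown libraries all outside the control range. From each list called by camera it adds the 2 called members with the smallest p that changed in the list's direction. It also adds 3 members of each pluripotency list and of the 3 lists with the smallest camera p. These 3 are the members with the smallest p in either direction, called or not. For knockdown against knockdown it takes 5 genes in each direction. Genes near the floor, such as ESRRB, PRAP1 and TNFRSF10A, give no usable fold, and none is given. Not every gene selected or examined is reported here. Other genes named here were chosen after their values were seen, as examples from the fixed lists or from genes called in 2 comparisons.

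Genes called in 2 knockdowns were counted by direction. The correlation and covariance of their fold changes, over genes of at least 4 log2 CPM, were set beside 20 simulated sets of unchanged groups against the same controls. The pipeline was tested on simulated data from 17984 genes with 200 changed per knockdown. At 4 log2 CPM or more it recovered, in the 4 knockdowns against controls, 81.8 to 91.7% of 2-fold changes, 11.1 to 26.7% of 1.5-fold changes and 100% of 4-fold changes. For SALL4 against VRTN it recovered 66.7% of 2-fold changes there and for DSCC1 against SEPHS1 80%. Among all simulated genes, 24 to 32% of 2-fold changes were recovered in these 6 comparisons. False calls were 9.21% of the calls for SALL4, 6.33% for VRTN, 15.1% for DSCC1 and 2.86% for SEPHS1, in 1 simulated set. Each share recovered at 4 log2 CPM or more rests on 8 to 16 simulated genes. The simulated libraries varied independently and lacked the difference between control replicates described below, so these rates need not hold for the real libraries.

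The alternatives were DESeq2 size factors and upper quartile scaling in edgeR, no filter and a stricter filter on low counts, a replicate block, a 2-fold minimum, only the groups compared, either control siRNA alone, DESeq2 1.42.0, limma-voom with quality weights, and leaving out each library in turn. Where that left a control group with 1 library, the fit assumed that it varies like the other groups. Added after the data were seen were replicate 1 or replicate 2 of the controls alone, a correction for each library's trend on transcript length and GC content (available for 99.2% of tested genes), leaving out 428 mitochondrial genes and copies, and leaving out SEPHS1 replicates 1 and 3 together. Figures were drawn with matplotlib 3.10.9.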

Results

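Polyadenylated RNA was sequenced from H9 cells, an established human embryonic stem cell line, here carrying EGFP at the REX1 promoter and grown without feeder cells. The 16 libraries fell into 6 groups. Pooled siRNAs were directed against SALL4 and VRTN, harvested at 48 h, and against DSCC1 and SEPHS1, harvested at 72 h, with 3 replicates each. The controls were 2 libraries with an siRNA against Renilla luciferase, called Luciferase here, and 2 with a control siRNA, called Control here. Library totals ran from 18597262 to 28662389 counts, and 14725 to 16634 genes per library had 10 or more counts. A floor of 3 counts corresponded to 0.105 to 0.161 normalised counts (CPM), which covers counting error only. Throughout, levels are TMM-normalised CPM with the SD, changes are log2 fold changes with the SE, and adjusted p values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 19772 genes. Each knockdown was set against the mean of both control groups, n = 3 against 4. The labels gave no harvest time for the controls, so time and knockdown could not be separated there. The siRNAs against SALL4, DSCC1, SEPHS1 and luciferase were made by enzymatic digestion and those against VRTN were synthetic. The Luciferase siRNA was therefore not of the same type as that against VRTN.

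The silenced transcripts themselves came first, as a check of each knockdown. VRTN, the vertnin gene of vertebral development (chromosome 14, 74303069 to 74360008, plus strand, GRCh38), fell to 21.3 ± 2.24 CPM (n = 3) from 143 ± 9.12 (n = 4), a log2 fold change of -2.75 (SE 0.13, adjusted p = 2.04e-16). SEPHS1, a selenophosphate synthetase paralogue (chromosome 10, 13317424 to 13348298, minus strand), fell to 14.9% of control, with a log2 fold change of -2.75 (SE 0.14, adjusted p = 9.09e-15). DSCC1, a subunit of the clamp loader used in sister chromatid cohesion (chromosome 8, 119833976 to 119856010, minus strand), was read 13 to 24 times per library against 70 to 129 times in the controls. Its level was 0.806 ± 0.18 CPM against 3.93 ± 0.853, a log2 fold change of -2.27 (SE 0.71), which was not called over all genes (adjusted p = 0.486). SALL4, a zinc finger factor of the pluripotency network (chromosome 20, 51782331 to 51802520, minus strand), stood at 213 ± 21.1 CPM against 274 ± 25.3. That was 77.9% of control, a log2 fold change of -0.36 (SE 0.11, adjusted p = 0.0562). Adjusted over the 4 targets alone, the p was 0.00237 for SALL4 and 0.00317 for DSCC1. DESeq2 called the SALL4 transcript lower (adjusted p = 0.00788), as did limma-voom (0.00563), and so did edgeR without Control replicate 1 (0.0292) or without SALL4 replicate 3 (0.0218). SALL4 was not called against Luciferase alone (adjusted p = 0.201), Control alone (0.199) or replicate 1 of the controls (log2 fold change -0.26, adjusted p = 0.664), nor corrected for length and GC (0.11). SEPHS1 also fell in SALL4 siRNA cells, to 207 ± 38.1 CPM (log2 fold change -0.99, SE 0.13, adjusted p = 1.13e-05). Its 3 libraries there lay between 174 and 249 CPM, and the 10 libraries of the other 4 groups lay between 317 and 440.

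**Figure D1:**
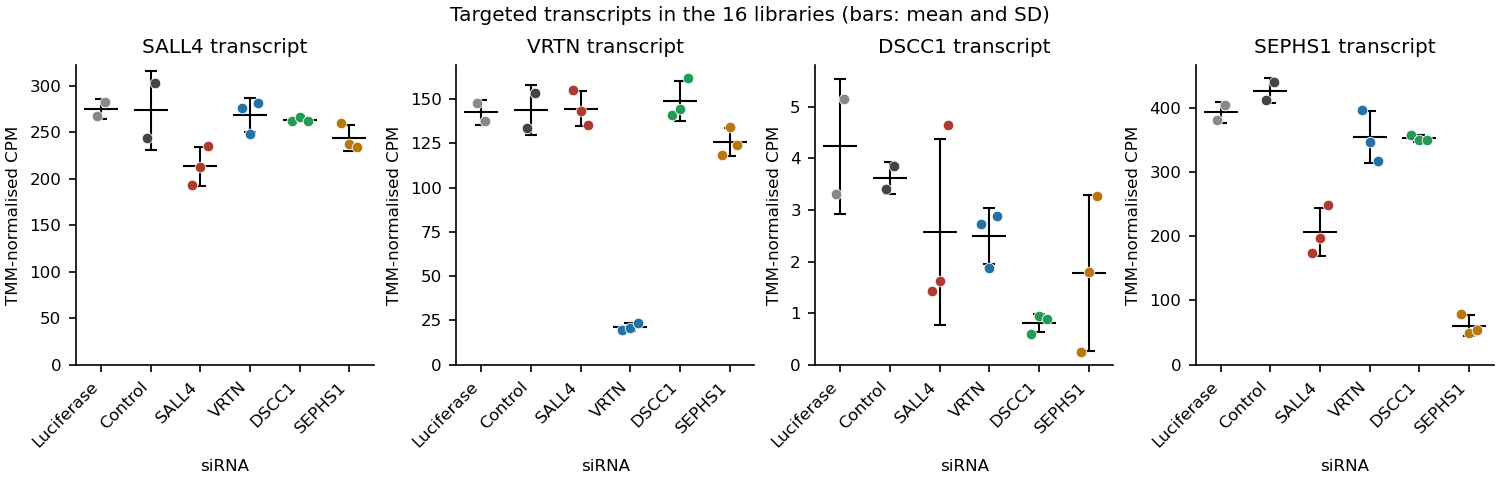
TMM-normalised CPM of SALL4, VRTN, DSCC1 and SEPHS1 in each of the 16 libraries, by siRNA, with the mean and SD per group as bars. SEPHS1 lies between 174 and 249 CPM in the SALL4 siRNA libraries, under the 317 to 440 CPM of the Luciferase, Control, VRTN and DSCC1 siRNA libraries.

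The SALL4 comparison asked which transcripts change when this pluripotency factor is targeted. ACTG2, smooth muscle gamma actin (chromosome 2, 73892314 to 73919865, plus strand), rose to 651 ± 70.1 CPM from 61.3 ± 12.6 (log2 fold change 3.41, SE 0.17, adjusted p = 7.61e-16). FEZF1, a forebrain transcription factor (chromosome 7, 122301394 to 122310691, minus strand), rose by 2.56 (SE 0.27, adjusted p = 1.62e-07). SLC16A10, an aromatic amino acid transporter, rose by 2.55 (SE 0.34, adjusted p = 1e-05). LRRC17, which encodes a secreted leucine-rich repeat protein, rose by 3.13. ARSL, an arylsulfatase of cartilage, rose by 3.13, and INSM1, a neuroendocrine zinc finger factor, rose by 3.08. Against replicate 1 and replicate 2 of the controls ARSL stood at 2.68 and 3.85, and INSM1 at 4.32 and 2.45. LRRC17 and INSM1 were not called against Luciferase alone (adjusted p = 0.0542 and 0.0911), nor was ARSL against Control alone (0.0673). PLEKHA6, which encodes an adherens junction protein (chromosome 1, 204218851 to 204377665, minus strand), fell by 2.34 (SE 0.30, adjusted p = 3.9e-06). HES3, a Notch-pathway repressor, fell by 1.97 (SE 0.30), and ST8SIA3, a neural sialyltransferase, fell by 1.92 (SE 0.34). POU2F3, a tuft cell factor, fell by 1.88 but was not called against replicate 2 of the controls (log2 fold change -1.34, adjusted p = 0.184). CHST4, a sulfotransferase, fell by 2.05, and its call was lost without Control replicate 2 (adjusted p = 0.0842), SALL4 replicate 1 (0.0619) or SALL4 replicate 2 (0.0868). GFY, an olfactory epithelium gene, fell by 1.96, and its call was lost without Luciferase replicate 2 (adjusted p = 0.0819) or SALL4 replicate 2 (0.0852).

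Pluripotency genes moved in both directions in SALL4 siRNA cells. Of 29 primed and core pluripotency genes, 1 was higher, 7 were lower and 21 were not called, and adjusted over the list alone 5 were higher and 9 lower. SALL2, a paralogue of SALL4 (chromosome 14, 21521081 to 21537216, minus strand), fell to 304 ± 50.8 CPM from 713 ± 69.4 (log2 fold change -1.23, SE 0.11, adjusted p = 3.74e-09). DNMT3B, the de novo DNA methyltransferase of stem cells (chromosome 20, 32762385 to 32809356, plus strand), fell to 459 ± 124 CPM from 1138 ± 169 (log2 fold change -1.31, SE 0.12, adjusted p = 1.7e-08). PRDM14, a repressor of differentiation genes (chromosome 8, 70051651 to 70071693, minus strand), fell by 1.10 (SE 0.12, adjusted p = 2.04e-07). POU5F1, NANOG and SOX2, the core factors, were singled out after their values were seen and were not called, with log2 fold changes of 0.26, 0.55 and 0.13 (SE 0.10, 0.16 and 0.11). The list as a whole was lower by camera (adjusted p = 0.000366; adjusted p = 0.0607 with an estimated correlation). Against replicate 1 of the controls only, camera's adjusted p for it was 0.0847. Of 11 naive pluripotency genes, 1 was lower and 10 were not called: ALPG, an alkaline phosphatase, had a log2 fold change of -1.08, lost without Luciferase replicate 2 (adjusted p = 0.0749), Control replicate 2 (0.146), SALL4 replicate 1 (0.0729) or SALL4 replicate 2 (0.298). It stood at -0.64 against replicate 1 of the controls (adjusted p = 0.593) and at -1.42 against replicate 2. KLF5 and KLF4, of the same list, were not called at 1.36 (SE 0.55) and 0.73 (SE 0.32).

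Signalling, epithelial and stress groups also moved in SALL4 siRNA cells. Of 14 NODAL and TGF-beta targets, 5 were higher and 1 was lower, and adjusted over the list alone 7 were higher and 1 lower. LEFTY2, an inhibitor of NODAL (chromosome 1, 225936598 to 225941489, minus strand), rose by 2.37 (SE 0.48, adjusted p = 0.0028). LEFTY2 was not called against Luciferase alone (adjusted p = 0.067). LEFTY1, its neighbour and paralogue, rose by 1.90 (SE 0.40), and its call was lost without SALL4 replicate 2 (adjusted p = 0.0597). LEFTY1 was not called against Control alone either, and stood at 2.11 against replicate 1 of the controls and at 1.71 against replicate 2. PMEPA1, a TGF-beta feedback gene, rose by 0.82, and its call was lost without SALL4 replicate 1 (adjusted p = 0.0797) or SALL4 replicate 2 (0.0847). PMEPA1 was not called against Luciferase alone or Control alone, and stood at 0.91 against replicate 1 of the controls and at 0.75 against replicate 2. Of 11 epithelial genes, 3 were lower and 8 were not called, and adjusted over the list alone 5 were lower. CDH1, which encodes E-cadherin (chromosome 16, 68737225 to 68835548, plus strand), fell to 148 ± 2.94 CPM from 253 ± 65.0 (log2 fold change -0.77, SE 0.14, adjusted p = 0.000995). CLDN7, a tight junction gene, fell by 1.34 (SE 0.27, adjusted p = 0.00219), and by 0.87 against replicate 1 of the controls only. Against replicate 1 of the controls only, CDH1 was not called (log2 fold change -0.42, adjusted p = 0.17). Of 30 ATF4 targets of the integrated stress response, 4 were lower and 26 were not called, and adjusted over the list alone 2 were higher and 7 lower. PCK2, the mitochondrial PEP carboxykinase, fell by 1.36 (SE 0.22, adjusted p = 0.00021), and SLC7A1, an arginine transporter, fell by 0.66 (SE 0.13, adjusted p = 0.0016). These 3 lists were called by camera and also with an estimated correlation, each at an adjusted p of 0.0474 with it.

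p53 targets, mesenchymal genes, ribosomal protein genes and replication genes were called as lists in SALL4 siRNA cells only at camera's preset correlation. Of 40 p53 targets, 9 were higher and 31 were not called, and adjusted over the list alone 11 were higher (camera adjusted p = 5.73e-11; adjusted p = 0.137 with an estimated correlation). TRIM22, an antiviral p53 target (chromosome 11, 5689689 to 5737089, plus strand), rose by 2.26 (SE 0.24, adjusted p = 1.12e-07). CCNG1, the cyclin G1 gene, rose by 1.22 (SE 0.18, adjusted p = 3.82e-05), and PLK2, a stress-induced kinase, rose by 1.75 (SE 0.29, adjusted p = 0.000262). Of 18 fibroblast and mesenchyme genes, 4 were higher and 1 was lower, and adjusted over the list alone 6 were higher and 1 lower (camera adjusted p = 8.29e-05; adjusted p = 0.268 with an estimated correlation). VIM, vimentin (chromosome 10, 17228259 to 17237593, plus strand), rose to 1103 ± 65.7 CPM from 508 ± 225 (log2 fold change 1.12, SE 0.18), and FN1, fibronectin, rose by 0.72 (SE 0.12). Against replicate 1 of the controls only, VIM rose by 0.66, and camera no longer called the mesenchyme list (adjusted p = 0.195). Of 64 cytosolic ribosomal protein genes, 7 were higher and adjusted over the list alone 12 were (camera adjusted p = 6.6e-07; adjusted p = 0.369 with an estimated correlation), with RPS27 at 0.54 (SE 0.11). Of 41 genes of G1/S and DNA replication, 3 were lower and adjusted over the list alone 8 were (camera adjusted p = 8.29e-05; adjusted p = 0.268 with an estimated correlation). MCM5, a helicase subunit, fell by 0.57, and its call was lost without SALL4 replicate 1 (adjusted p = 0.17) or SALL4 replicate 2 (0.18).

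A further 7 lists passed camera in SALL4 siRNA cells, each losing its call without at least 1 library and at an adjusted p of 0.116 to 0.298 with an estimated correlation. Neuroectoderm genes included SOX3, an early neural factor (chromosome X, 140502985 to 140505116, minus strand), which rose by 1.40 (SE 0.21, adjusted p = 8.1e-05). That list had 1 of 24 genes higher and 1 lower (adjusted over the list alone 3 and 1), and was lost without Luciferase replicate 2 (adjusted p = 0.116), Control replicate 2 (0.0741) or SALL4 replicate 2 (0.0636). Primitive streak genes had 1 of 15 higher and were lost without Luciferase replicate 2 (adjusted p = 0.119), Control replicate 2 (0.0741) or SALL4 replicate 2 (0.0773). BMP targets had 1 of 12 higher and were lost without SALL4 replicate 1 (adjusted p = 0.126). Lateral mesoderm genes had 1 of 15 higher and were lost without Luciferase replicate 2 (adjusted p = 0.0557), SALL4 replicate 1 (0.122) or SALL4 replicate 2 (0.116). Nuclear OXPHOS genes had 2 of 31 higher and were lost without SALL4 replicate 2 (adjusted p = 0.0649) or SALL4 replicate 3 (0.125). Polycomb and DNA methylation genes had 2 of 20 lower, DNMT3B among them, and were lost without Luciferase replicate 1 (adjusted p = 0.0892), Control replicate 2 (0.0809), SALL4 replicate 1 (0.0718) or SALL4 replicate 2 (0.0506). Homologous recombination genes had 1 of 28 lower and were lost without SALL4 replicate 1 (adjusted p = 0.193) or SALL4 replicate 2 (0.0649). Of the genes called in these lists, WNT3, SMAD7, KDR, JARID2 and PALB2 each lost their call without SALL4 replicate 1 (adjusted p = 0.117, 0.444, 0.12, 0.0625 and 0.187) and without SALL4 replicate 2 (0.273, 0.0704, 0.102, 0.0528 and 0.0557). WNT3, SMAD7 and PALB2 also lost it without Control replicate 2 (0.0707, 0.0516 and 0.207), SMAD7 and PALB2 without Luciferase replicate 2 (0.058 and 0.156), and JARID2 and PALB2 without SALL4 replicate 3 (0.07 and 0.131).

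In all, 590 genes were called in SALL4 siRNA cells, 366 higher and 224 lower, of which 158 rose and 68 fell at least 2-fold. In 501 of the 590 the 3 knockdown libraries all lay outside the range of the 4 controls, and over all genes 13.7% did so, where chance gives 5.71%. The count was 275 without SALL4 replicate 1, 291 without SALL4 replicate 2 and 924 without SALL4 replicate 3.

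The VRTN comparison asked the same of a gene known from vertebral development. UTF1, a chromatin factor of pluripotent cells (chromosome 10, 133230274 to 133231558, plus strand), fell to 28.7 ± 2.69 CPM from 66.0 ± 5.09 (log2 fold change -1.20, SE 0.16, adjusted p = 1.28e-05). SLC7A5, a large neutral amino acid transporter (chromosome 16, 87830023 to 87869488, minus strand), fell to 622 ± 116 CPM from 1330 ± 190 (log2 fold change -1.10, SE 0.12, adjusted p = 1.07e-06). SERPINB9, a granzyme B inhibitor (chromosome 6, 2887266 to 2903280, minus strand), rose to 317 ± 167 CPM from 58.6 ± 29.3 (log2 fold change 2.43, SE 0.29, adjusted p = 2.99e-06). SERPINB9 stood at 3.24 against replicate 1 of the controls and at 1.93 against replicate 2. MAML2, a Notch coactivator (chromosome 11, 95976598 to 96343180, minus strand), rose by 1.98 (SE 0.29, adjusted p = 0.0001). SLC16A10 rose by 1.88 (SE 0.34), and against Luciferase alone it stood at 1.77 and was not called (adjusted p = 0.0517). FAM20A, a secretory pathway pseudokinase (chromosome 17, 68535113 to 68601389, minus strand), fell by 2.46 (SE 0.37), and DMTN, an actin-binding protein of red cells, fell by 2.37 (SE 0.45). FOXJ1, a cilia regulator, fell by 2.64 (SE 0.43), and CRYBG1, a crystallin-like gene, fell by 2.36 (SE 0.41). limma-voom called none of these last 4 genes (adjusted p = 0.0592, 0.0647, 0.0906 and 0.0666). FOXJ1 and CRYBG1 were also not called against replicate 1 of the controls (adjusted p = 0.0552 and 0.0662). ACAP1, a trafficking GAP, fell by 2.18, and its call was lost without VRTN replicate 1 (adjusted p = 0.0905) or VRTN replicate 2 (0.0713). The calls of the remaining large rises were lost without VRTN replicate 3. CST4, a salivary cystatin, rose by 2.33 but stood at 0.95 without it (adjusted p = 0.621). MYB, a progenitor factor, rose by 2.43 but had an adjusted p of 0.278 without it. SOX21, a neural factor, rose by 2.28 and had an adjusted p of 0.158 without it and of 0.0844 without VRTN replicate 2.

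Epithelial genes were lower in VRTN siRNA cells, with 2 of 11 lower and 9 not called, and adjusted over the list alone 6 lower. The list was called by camera (adjusted p = 1.47e-06; adjusted p = 0.0132 with an estimated correlation). KRT8, a simple epithelial keratin (chromosome 12, 52897187 to 52949954, minus strand), fell to 169 ± 3.73 CPM from 261 ± 25.1 (log2 fold change -0.62, SE 0.13, adjusted p = 0.00594). KRT8 was not called against Luciferase alone (adjusted p = 0.107). CDH1 fell by 0.72 (SE 0.14, adjusted p = 0.00404), and its call was lost without VRTN replicate 2 (adjusted p = 0.0597) and against replicate 1 of the controls (log2 fold change -0.37, adjusted p = 0.412). KRT18, the partner of KRT8, was not called at -0.44 (SE 0.12). Pluripotency genes did not move 1 way: of 29, ZIC2 and DPPA4 were higher, UTF1 and CDH1 lower and 25 not called, and adjusted over the list alone 6 were higher and 5 lower (camera adjusted p = 0.938). The ZIC2 call was lost without Luciferase replicate 2 (adjusted p = 0.0986), Control replicate 2 (0.164) or VRTN replicate 3 (0.141). Among naive genes, ALPG fell by 1.46, lost without VRTN replicate 1 (adjusted p = 0.088) or VRTN replicate 2 (0.0996) and against replicate 1 of the controls (-1.02, adjusted p = 0.146).

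Of the other 7 lists called in VRTN siRNA cells, none held with an estimated correlation. Of 64 ribosomal protein genes, RPL38 and RPS27 were higher and 62 were not called, and adjusted over the list alone 10 were higher (camera adjusted p = 4.47e-10; adjusted p = 0.613 with an estimated correlation). RPL38 and RPS27 lost their calls without VRTN replicate 1 (adjusted p = 0.0677 and 0.166) or VRTN replicate 3 (0.16 and 0.0716), RPL38 also without Control replicate 2 (0.0617), and RPS27 without Luciferase replicate 2 (0.0756) or Control replicate 1 (0.0665). Corrected for length and GC, RPL38 stood at 0.29 (adjusted p = 0.191) and RPS27 at 0.27 (0.346). Of 29 hypoxia and glycolysis genes, 2 were lower, VEGFA among them, and adjusted over the list alone 1 was higher and 5 lower (camera adjusted p = 0.00702; adjusted p = 0.0877 with an estimated correlation). VEGFA, the endothelial growth factor, fell by 1.18 (SE 0.25), and its call was lost without VRTN replicate 1 (adjusted p = 0.0749) or VRTN replicate 2 (0.1). Of 30 ATF4 targets, 3 were lower, SLC7A5 and SLC7A1 among them, and adjusted over the list alone 4 were (camera adjusted p = 0.00702; adjusted p = 0.125 with an estimated correlation). That list was lost without VRTN replicate 1 (adjusted p = 0.0514) or VRTN replicate 2 (0.0852). Of 18 mesenchyme genes, 3 were higher and 2 lower, and adjusted over the list alone 4 and 2 (camera adjusted p = 0.00702; adjusted p = 0.765 with an estimated correlation). FN1 rose by 0.89 (SE 0.12, adjusted p = 1.89e-05), COL1A1, a fibrillar collagen, fell by 1.28 (SE 0.18), and CDH2, N-cadherin, rose by 1.11. CDH2 stood at 0.70 against replicate 1 of the controls (adjusted p = 0.135) and at 1.70 against replicate 2. Its call was also lost without VRTN replicate 1 (adjusted p = 0.0798) or VRTN replicate 2 (0.0828), and the mesenchyme list without Luciferase replicate 2 (0.255), Control replicate 2 (0.545) or VRTN replicate 2 (0.0993). Of 37 mitotic genes, PTTG1, securin, rose by 0.78 (SE 0.14; not called against Control alone, adjusted p = 0.14), and the list was lost without VRTN replicate 2 (adjusted p = 0.0681; adjusted p = 0.345 with an estimated correlation). Of 13 mitochondrial mRNAs and 14 NODAL and TGF-beta targets none was called, where edgeR gave 3 of the latter higher adjusted over the list alone. The mitochondrial list (camera adjusted p = 0.00361; adjusted p = 0.933 with an estimated correlation) was lost without Luciferase replicate 1 (0.225), Control replicate 2 (0.0797), VRTN replicate 2 (0.179) or VRTN replicate 3 (0.142). The NODAL list (camera adjusted p = 0.0223; adjusted p = 0.388 with an estimated correlation) was lost without Luciferase replicate 1 (0.0891), Control replicate 1 (0.131) or VRTN replicate 3 (0.0721).

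The VRTN comparison called 223 genes, 88 higher and 135 lower, with 32 up and 46 down at least 2-fold. With a correction for length and GC 100 were higher and 101 lower. In 217 of the 223 the groups did not overlap, and over all genes 12.0% did not, against 5.71% by chance. The count was 141 without VRTN replicate 1, 140 without VRTN replicate 2 and 135 without VRTN replicate 3.

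The DSCC1 comparison asked the same of a cohesion and replication gene, and called 9 genes, all higher. POLR2L, a subunit shared by the RNA polymerases (chromosome 11, 837356 to 842545, minus strand), rose to 116 ± 6.37 CPM from 62.4 ± 2.23 (log2 fold change 0.90, SE 0.12, adjusted p = 0.000255). RPL23AP74, a ribosomal protein pseudogene, rose by 0.91 (SE 0.12, adjusted p = 0.000255), a value that is uncertain because its sequence is close to that of other copies. Against the same controls POLR2L and RPL23AP74 were also called higher in SALL4 (0.59 and 0.84), VRTN (0.52 and 0.57) and SEPHS1 siRNA cells (0.77 and 1.20). Their rise was thus not particular to DSCC1 siRNA. NDUFA3, a complex I subunit, rose by 0.67 (SE 0.13), the ribosomal protein genes RPS14, RPL18, RPL28 and RPL41 rose by 0.54 to 0.60, and the complex I subunit MT-ND3 rose by 0.75 (SE 0.15), at adjusted p of 0.047 to 0.0482. The remaining gene, ENSG00000279483, rose by 0.57. RPL41 and ENSG00000279483 lay outside the naming rule and were added after their values were seen. Of 26 cohesin and cohesion genes and 41 genes of G1/S and DNA replication, edgeR called 0, also over each list alone, and camera's adjusted p values were 0.207 and 0.405. Of 13 mitochondrial mRNAs, 1 was higher and adjusted over the list alone 9 were (camera adjusted p = 6.28e-14; adjusted p = 0.37 with an estimated correlation). Of 64 ribosomal protein genes, 3 were higher and adjusted over the list alone 11 were (camera adjusted p = 2.27e-09; adjusted p = 0.48 with an estimated correlation). The ribosomal list was called higher by camera in SALL4, VRTN and SEPHS1 siRNA cells too, against the same controls. p53 targets were called lower as a list with 0 of 40 called, CDKN1A, a cell cycle inhibitor, at -0.77 (SE 0.32). Against replicate 1 of the controls CDKN1A was called at -1.16 (adjusted p = 0.00416), and against replicate 2 it stood at -0.23 (adjusted p = 1). The p53 list was lost without Luciferase replicate 1 (adjusted p = 0.242), Control replicate 1 (0.0815) or DSCC1 replicate 2 (0.0613; adjusted p = 0.534 with an estimated correlation). Nuclear OXPHOS genes, with 0 of 31 called, were lost without DSCC1 replicate 2 (adjusted p = 0.119; adjusted p = 0.48 with an estimated correlation). Glutathione genes, with 0 of 23 called and 1 higher adjusted over the list alone, were lost without any of 5 libraries at 0.0613 to 0.128 (adjusted p = 0.37 with an estimated correlation). Those libraries were the 3 DSCC1 libraries, Luciferase replicate 2 and Control replicate 2.

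edgeR gave 1155 genes an unadjusted p under 0.05 in the DSCC1 comparison, DESeq2 called 52 and limma-voom 41. In all 9 called genes the groups did not overlap, and over all genes 9.10% did not, against 5.71% by chance. The count was 2 without any 1 of the DSCC1 libraries, DSCC1 replicate 1, 2 or 3, and it was 98 without Luciferase replicate 2, 47 without Control replicate 2 and 19 without Control replicate 1. The direction was mixed in some of these fits, with 56 higher and 42 lower without Luciferase replicate 2 and 27 and 20 without Control replicate 2. With no low-count filter it was 55 and 44, and against replicate 1 of the controls 54 and 55. POLR2L and RPL23AP74 were the only genes of the 7 under the naming rule to be called in every fit that left out 1 library. NDUFA3 had adjusted p of 0.323, 0.23 and 0.239 without DSCC1 replicate 1, 2 and 3, and MT-ND3 of 0.224, 0.194 and 0.663. RPS14 had 0.323, 0.23 and 0.123, RPL18 had 0.323, 0.23 and 0.241, and RPL28 had 0.293, 0.0846 and 0.241 without the same libraries. Without Luciferase replicate 1 the adjusted p was 0.0696 for NDUFA3, 0.0751 for RPS14 and 0.0751 for RPL18, and without Control replicate 1 it was 0.0925 for NDUFA3 and 0.0998 for RPS14.

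The SEPHS1 comparison asked the same of a gene of selenium metabolism. INPP5J, an inositol phosphatase (chromosome 22, 31122731 to 31134696, plus strand), fell to 0.807 ± 0.417 CPM from 12.2 ± 2.37 (log2 fold change -3.88, SE 0.35, adjusted p = 1.81e-08). IKBKE, an interferon pathway kinase (chromosome 1, 206470476 to 206496889, plus strand), fell by 3.71 (SE 0.63), MCHR1, a hypothalamic peptide receptor, by 3.34 (SE 0.59) and TRANK1, an ankyrin repeat gene, by 3.03 (SE 0.48). limma-voom did not call these 3 genes (adjusted p = 0.0722, 0.321 and 0.139). SEPHS1P4, a processed copy of SEPHS1 on chromosome X, fell by 3.23 (SE 0.59), a value that is uncertain because it shares sequence with SEPHS1. TNC, tenascin C, fell by 3.07 (SE 0.79), and its call was lost without SEPHS1 replicate 1 (adjusted p = 0.051), SEPHS1 replicate 2 (0.14) or SEPHS1 replicate 3 (0.204). TNC stood at -1.30 against replicate 2 of the controls (adjusted p = 0.202). Of 24 extracellular matrix and adhesion genes, 2 were lower and 22 were not called, and adjusted over the list alone 6 were lower. LAMA5, a basement membrane laminin (chromosome 20, 62307955 to 62367312, minus strand), fell to 220 ± 10.5 CPM from 375 ± 44.9 (log2 fold change -0.77, SE 0.13, adjusted p = 0.000605). HSPG2, perlecan, fell by 1.06 (SE 0.19, adjusted p = 0.000996). Corrected for length and GC, LAMA5 stood at -0.39 (adjusted p = 0.0287) and HSPG2 at -0.64 (0.0324), and HSPG2 was not called without SEPHS1 replicates 1 and 3 together (-0.80, adjusted p = 0.123). This list (camera adjusted p = 0.00798; adjusted p = 0.277 with an estimated correlation) was lost without SEPHS1 replicate 2 (0.109). Of 23 selenoprotein genes and 8 genes of selenocysteine synthesis and insertion, edgeR called 0. Adjusted over the list alone, 1 selenoprotein gene was higher, and camera's adjusted p values were 0.682 and 0.746.

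Mitochondrial mRNAs and some ribosomal protein transcripts were called higher in SEPHS1 siRNA cells, and neither list was called with an estimated correlation. Of 13 mitochondrial mRNAs, 11 were higher and 2 were not called, and adjusted over the list alone 12 were higher (camera adjusted p = 1.57e-32; adjusted p = 0.117 with an estimated correlation). MT-ND3 (mitochondrial genome, 10059 to 10404) rose to 7391 ± 2438 CPM from 2401 ± 333 (log2 fold change 1.63, SE 0.15, adjusted p = 2.93e-08). MT-ATP8, an ATP synthase subunit, rose by 1.30 (SE 0.16, adjusted p = 5.38e-06; 0.82 corrected for length and GC), and MT-ND2, a complex I subunit, rose by 1.06 (SE 0.14, adjusted p = 2.07e-05). Mitochondrial genes took 41.1 ± 3.86% of the counts (n = 3), against 30.5 ± 3.65% in Luciferase (n = 2) and 32.0 ± 1.98% in Control (n = 2). DSCC1 siRNA cells, also harvested at 72 h, had 35.8 ± 2.95%, and SALL4 and VRTN siRNA cells had 30.8 ± 4.21% and 34.3 ± 4.43%. Of 64 cytosolic ribosomal protein genes, 16 were higher and 48 were not called, and adjusted over the list alone 37 were higher and 2 lower (camera adjusted p = 7.47e-22; adjusted p = 0.239 with an estimated correlation). RPL23 (chromosome 17, 38847865 to 38853843, minus strand) rose to 78.1 ± 37.6 CPM from 23.3 ± 4.52 (log2 fold change 1.74, SE 0.23, adjusted p = 1.56e-05), and ATP5MF, a nuclear ATP synthase subunit, rose by 1.63 (SE 0.23, adjusted p = 4.86e-05). Nuclear copies of mitochondrial genes, MTND4P35 and MTATP8P1, rose by 2.02 (SE 0.29) and 1.76 (SE 0.27), uncertain because they may share reads with the mitochondrial genome, which was not tested. The mitochondrial tRNA gene MT-TF rose by 2.37, and its call was lost without SEPHS1 replicate 3 (adjusted p = 0.192). Nuclear OXPHOS genes were called higher as a list with 1 of 31 higher and 4 adjusted over the list alone (camera adjusted p = 0.000503; adjusted p = 0.239 with an estimated correlation). Of 37 mitotic genes, PTTG1 was higher at 0.66 (SE 0.14; not called against Control alone, adjusted p = 0.287), 2 were higher adjusted over the list alone, and the list was lost without Luciferase replicate 1 (adjusted p = 0.0688), Control replicate 2 (0.105) or SEPHS1 replicate 1 (0.177; adjusted p = 0.422 with an estimated correlation).

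**Figure D2:**
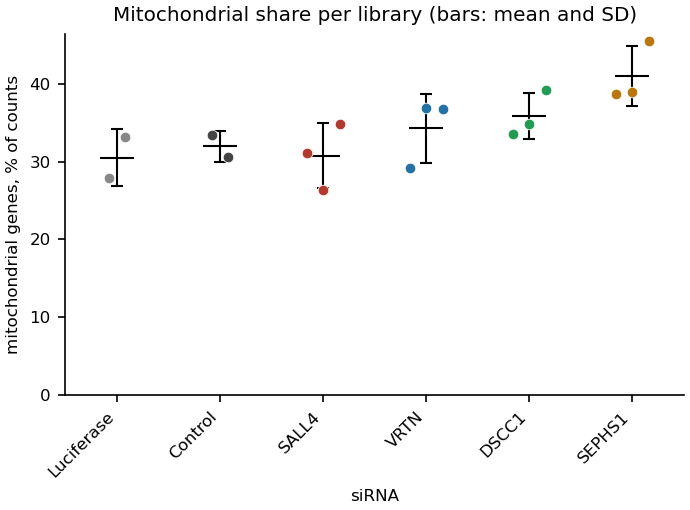
Share of each library's counts on mitochondrial genes, in percent, by siRNA, with the mean and SD per group as bars. The SEPHS1 siRNA libraries average 41.1%, and all 16 libraries lie between 26.4 and 45.5%.

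Pluripotency genes were mostly not called in SEPHS1 siRNA cells, with 1 of 29 higher and 1 lower, and 3 and 2 adjusted over the list alone. TERF1, a telomere protein gene, rose by 0.77 (SE 0.16), lost without SEPHS1 replicate 3 (adjusted p = 0.0843). It stood at 1.17 against replicate 1 of the controls and at 0.46 against replicate 2, where it was not called (adjusted p = 0.197), nor was it against Control alone (0.207). SALL2 fell by 0.46 (SE 0.11), lost without Luciferase replicate 1 (adjusted p = 0.0932), SEPHS1 replicate 1 (0.0673) or SEPHS1 replicate 3 (0.123). SALL2 was not called either when corrected for length and GC (-0.29, adjusted p = 0.234) or against replicate 2 of the controls (-0.42, 0.136). POU5F1, NANOG and SOX2 stood at 0.09, 0.07 and 0.10 and were not called. The comparison called 303 genes, 119 higher and 184 lower, with 29 up and 95 down at least 2-fold. limma-voom called 97 higher and 61 lower, and with a correction for length and GC 104 were higher and 99 lower. In 293 of the 303 the groups did not overlap, and over all genes 2573 did not, where chance gives 5.71% of 19772. SEPHS1 replicates 1 and 3 had low complexity: the most frequent count among lightly read genes was 19 and 20 reads, against 9 to 12 in 13 of the other libraries and 16 in VRTN replicate 3. The number of called genes was 135 without SEPHS1 replicate 3, 472 without Luciferase replicate 2, and 94 without SEPHS1 replicates 1 and 3 together.

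SALL4 and VRTN siRNA cells shared a harvest time and could be compared without the controls, n = 3 against 3. The SALL4 siRNAs were made by enzymatic digestion and the VRTN siRNAs were synthetic, so target and siRNA type could not be separated here. ACTG2 was higher in SALL4 siRNA cells, at 651 ± 70.1 CPM against 16.7 ± 5.41 in VRTN siRNA cells (log2 fold change 5.28, SE 0.20, adjusted p = 7.28e-19). LCP1, the actin bundler plastin (chromosome 13, 46125920 to 46211871, minus strand), was higher by 4.16 (SE 0.29), FAM20A by 4.07 (SE 0.40), DMTN by 3.55 (SE 0.48) and TRPC4, a calcium channel, by 3.38 (SE 0.48). FOXA2, an endoderm factor, stood at -2.57 (SE 0.53, adjusted p = 0.00354; 0.0895 with only the groups compared), HES3 at -2.11 (SE 0.32, adjusted p = 5.94e-05) and CCKBR, a gastrin receptor, at -1.97 (SE 0.30). FGF4, a stem cell growth factor, at -1.75 (SE 0.44), lost its call without SALL4 replicate 1 (adjusted p = 0.141), SALL4 replicate 2 (0.0882), VRTN replicate 1 (0.0538) or VRTN replicate 3 (0.118). CHST4, at -2.04 (SE 0.48), lost it without SALL4 replicate 1 (adjusted p = 0.0846), SALL4 replicate 2 (0.113) or VRTN replicate 1 (0.0861). Of 40 p53 targets, 9 were higher in SALL4 siRNA cells and 31 were not called, and adjusted over the list alone 14 were higher (camera adjusted p = 7.19e-12; adjusted p = 0.101 with an estimated correlation). CDKN1A was higher by 2.26 (SE 0.35, adjusted p = 9.78e-05) and MDM2, the p53 ubiquitin ligase, by 1.03 (SE 0.19). Of 29 primed pluripotency genes, 2 were higher and 6 lower, and adjusted over the list alone 2 and 9 (camera adjusted p = 0.000798; adjusted p = 0.101 with an estimated correlation). DNMT3B stood at -1.25 (SE 0.13), PRDM14 at -1.05 (SE 0.13) and UTF1 at 1.12 (SE 0.16). SEPHS1 itself was lower in SALL4 siRNA cells, at -0.78 (SE 0.14, adjusted p = 0.000779). The comparison called 482 genes, 343 higher and 139 lower. In 432 of them the groups did not overlap, and over all genes 16.2% did not, against 10% by chance. The count was 248 without SALL4 replicate 1, 275 without SALL4 replicate 2, 879 without SALL4 replicate 3, 299 without VRTN replicate 1 and 304 without VRTN replicate 2.

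Against the controls, 73 genes were called in the same direction in SALL4 and VRTN siRNA cells, 42 higher and 31 lower, where independence gives 1.63 and 1.53. SERPINB9, FN1, MAML2 and the collagens COL6A1 and COL6A2 were higher in both, while COL1A1, POU2F3 and the stem cell oncogene MYCN were lower in both. COL6A1 rose by 1.89 (SE 0.15) in SALL4 and 0.62 (SE 0.14) in VRTN siRNA cells, and MYCN fell by 0.55 and 0.65. A further 11 genes went in opposite directions. ACTG2 rose by 3.41 and fell by 1.87, LCP1 rose by 2.0 and fell by 2.16, and FAM20A rose by 1.60 and fell by 2.46. With 1 knockdown set against Luciferase and the other against Control, so that no control was used in both, 25 and 17 genes were shared. Each contrast then used 2 control libraries and called fewer genes, 236 or 280 for SALL4 and 89 or 95 for VRTN. Lower shared counts with separate controls can therefore not be put down to the separation alone. Across 5639 genes, which are not independent replicates, the fold changes of SALL4 and VRTN siRNA cells against all 4 controls correlated at 0.341. Simulated unchanged groups against the same controls correlated at 0.428, since shared controls alone give a correlation. The covariance of the fold changes was 0.0342, against 0.0162 for the simulated groups. It was 0.0330 for VRTN and SEPHS1 and 0.0387 for DSCC1 and SEPHS1, against a simulated 0.0161 each. For SALL4 and SEPHS1 (0.0148, simulated 0.0163), SALL4 and DSCC1 (0.0118, simulated 0.0162) and VRTN and DSCC1 (0.0141, simulated 0.0162) it lay under the simulated value. The simulated libraries varied independently and lacked the difference between control replicates described below. A covariance over or under the simulated value therefore does not tell a shared response from that difference. Separate controls keep it too, as each control siRNA has both replicate numbers. Subject to that, fold changes with separate controls correlated at 0.292 and 0.215 for SALL4 and VRTN. The values were 0.286 and 0.250 for VRTN and SEPHS1, and 0.4245 and 0.419 for DSCC1 and SEPHS1. They were 0.115 and 0.00646 for SALL4 and DSCC1, and 0.115 and 0.0250 for SALL4 and SEPHS1. VRTN and DSCC1 gave 0.116 and 0.0857. SALL4 and SEPHS1 siRNA cells shared 45 genes in direction and 12 in opposition, among the latter the ETS family gene ETS1 (1.43 and -1.07). With separate controls they shared 9 and 10. VRTN and SEPHS1 shared 26 genes, and with separate controls 1 and 2. DSCC1 shared all 9 of its genes with SEPHS1, 7 with SALL4 and 2 with VRTN, and with separate controls 2 and 2, 2 and 1, and 0 and 0.

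**Figure D3:**
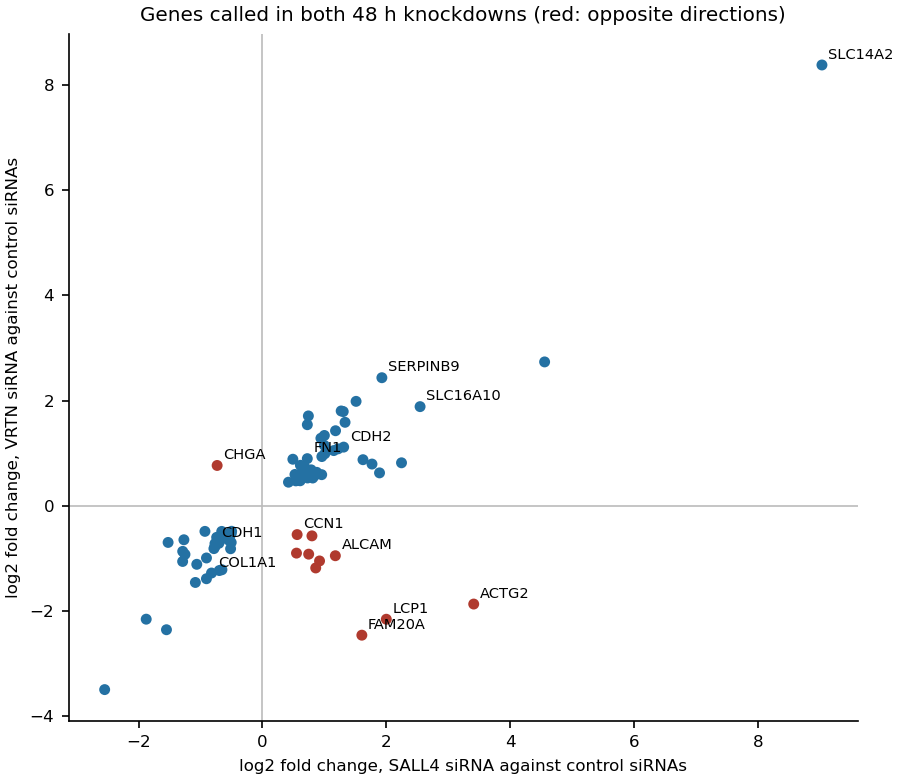
Log2 fold change in SALL4 siRNA cells (horizontal) and in VRTN siRNA cells (vertical), each against the control siRNAs, 1 point per gene called in both, with opposite directions in red. Of these genes 73 share a direction and 11, among them ACTG2, LCP1 and FAM20A, do not; the position of SLC14A2 depends on the fitted prior, as its 4 control libraries hold 0 reads.

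DSCC1 and SEPHS1 siRNA cells, both harvested at 72 h, were also compared without the controls, n = 3 against 3. INPP5J was higher in DSCC1 siRNA cells, at 18.1 ± 1.69 CPM against 0.807 ± 0.417 in SEPHS1 siRNA cells (log2 fold change 4.47, SE 0.37, adjusted p = 1.22e-09), and TRANK1 was higher by 3.09 (SE 0.49). limma-voom called neither (adjusted p = 0.0581 and 0.234). STK4, a Hippo pathway kinase (chromosome 20, 44966474 to 45079959, plus strand), was lower, at 30.7 ± 2.53 CPM against 59.4 ± 4.76 (log2 fold change -0.95, SE 0.15, adjusted p = 0.00102). MT-ND3 stood at -0.87 (SE 0.16), and its call was lost without DSCC1 replicate 1 (adjusted p = 0.123), DSCC1 replicate 2 (0.0881) or SEPHS1 replicate 3 (0.119). Corrected for length and GC, MT-ND3 stood at -0.59 (adjusted p = 0.242). IKBKE was higher by 3.26, lost without DSCC1 replicate 1 (adjusted p = 0.0617), DSCC1 replicate 3 (0.0791), SEPHS1 replicate 2 (0.0513) or SEPHS1 replicate 3 (0.0515). The selenoprotein gene SELENOF stood at -1.07, lost without DSCC1 replicate 1 (adjusted p = 0.19), DSCC1 replicate 2 (0.0698), SEPHS1 replicate 1 (0.052) or SEPHS1 replicate 3 (0.0738). TMEM41B, HMCN2, CLDND1 and SEPHS1P4 were also selected by the rule for named genes, at -1.47, 2.62, -0.86 and 2.81. All but HMCN2 lost their calls without DSCC1 replicate 1 (adjusted p = 0.127, 0.122 and 0.0736) and SEPHS1 replicate 3 (0.101, 0.0738 and 0.0969), and all 4 without DSCC1 replicate 2 (0.204, 0.0887, 0.0551 and 0.156). Without DSCC1 replicate 3 the values of TMEM41B, HMCN2 and CLDND1 were 0.127, 0.0596 and 0.197, and without SEPHS1 replicate 2 they were 0.0587, 0.0587 and 0.0575. Without SEPHS1 replicate 1 the values of TMEM41B, HMCN2 and SEPHS1P4 were 0.0683, 0.0598 and 0.123. Of 13 mitochondrial mRNAs, 1 was lower in DSCC1 siRNA cells and 12 were not called, and adjusted over the list alone 6 were lower (camera adjusted p = 1.04e-08; adjusted p = 0.774 with an estimated correlation). Ribosomal protein genes, with 0 of 64 called, were lower as a list (camera adjusted p = 5.77e-06; adjusted p = 0.774 with an estimated correlation). The comparison called 53 genes, 47 higher and 6 lower, where DESeq2 called 188 and limma-voom 24. In all 53 the groups did not overlap, and over all genes 14.0% did not, against 10% by chance. The count was 24 without DSCC1 replicate 1, 22 without DSCC1 replicate 2 and 27 without DSCC1 replicate 3.

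Control and Luciferase cells gave the background between the 2 control siRNAs, n = 2 against 2. edgeR called 0 genes, with 211 at an unadjusted p under 0.05, DESeq2 called 0 and limma-voom 0, and edgeR called 1 without Control replicate 1 and 1 without Control replicate 2. camera nonetheless called 5 lists with 0 genes called, at adjusted p of 0.027 to 0.0462 and of 0.551 to 0.965 with an estimated correlation. Epithelial genes and mitochondrial mRNAs were among them, so list calls of that size occurred between control siRNAs too. The controls also differed by replicate number, a comparison made after the data were seen. VIM stood at 757 and 640 CPM in replicate 1 of Luciferase and Control and at 319 and 316 in replicate 2. CDH1 stood at 195 and 200 CPM in replicate 1 and at 289 and 325 in replicate 2. A fit over 16 libraries called 3 genes between the replicate numbers, and a fit over the 4 control libraries alone called 148, 46 higher and 102 lower in replicate 2. The latter fit had a term for each control siRNA and 1 for the replicate number. That left almost no residual freedom, so its calls rest mostly on the spread shared between genes. Set against replicate 1 or replicate 2 of the controls only, SALL4 siRNA cells had 342 and 586 called genes, VRTN 159 and 241, DSCC1 109 and 4, and SEPHS1 373 and 137.

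**Figure D4:**
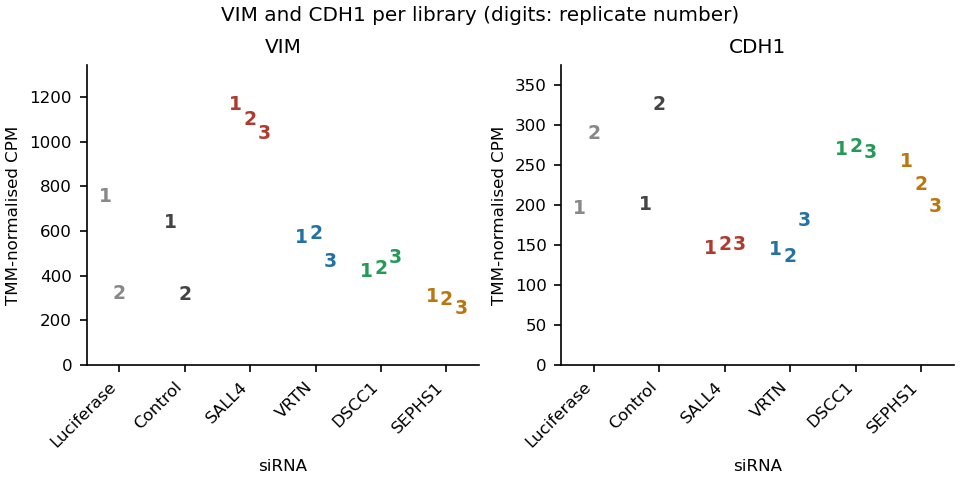
TMM-normalised CPM of VIM and CDH1 in each of the 16 libraries, by siRNA, with the digit giving the replicate number. In both control groups replicate 1 lies above replicate 2 for VIM and under it for CDH1.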

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

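All tests in this part were chosen after the patterns they bear on were seen. For 2 of them the prediction is recorded as written before the test: the length and GC test of the control replicates and the carry-over test of SEPHS1.

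Among 119 measures in the 4 control libraries, 2 of each control siRNA, 7 had 1 library whose gap to the nearest of the other 3, as a share of the whole range, passed Dixon's 95% critical value, where chance gives about 1 in 20. SLC16A10 stood at 1.97 CPM in Control replicate 2 (2.93 to 3.06 in the others), COX7C at 20.9 in Luciferase replicate 2 (24.7 to 25.3) and LAMA5 at 442 in Luciferase replicate 1 (349 to 358). KLF4 stood at 8.32 in Luciferase replicate 2 (4.53 to 4.71), SELENOF at 12.7 in Control replicate 1 (17.2 to 17.9) and IKBKE at 9.72 in Control replicate 1 (5.05 to 5.65). PRAP1 stood at 0.283 in Luciferase replicate 1 and was listed at 0 in the others. Groups of 3 libraries were not tested in this way.

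In both control siRNAs replicate 2 differed from replicate 1 in a like way across genes. The 2 differences correlated at 0.338 over 5526 genes, above the highest of 20 simulated sets (0.0139), which argued against noise independent between genes. The simulated genes were drawn independently, so a chance alignment of variation shared between genes cannot be excluded. With each library's length and GC trend removed the correlation was 0.353, which argued against that trend. VRTN replicate 3 departed from the other VRTN libraries along the same difference (correlation 0.340), as did SALL4 replicate 3 from the other SALL4 libraries (0.395), which argued against harvest time as labelled, since all 6 were labelled 48 h. The DSCC1 and SEPHS1 libraries lay between -0.0123 and 0.0169, while the 72 h knockdowns minus the 48 h knockdowns correlated with it at 0.368. A batch, culture day or time in culture that the labels do not give may underlie it and stays open, and no biological explanation was tested, as the labels set no groups within the controls.

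Mitochondrial mRNAs were higher in SEPHS1 siRNA cells, with a median log2 fold change of 0.73 over 13 mRNAs (quartiles 0.65 and 1.06) and 11 called. With each library's length and GC trend removed the median was 0.65 (quartiles 0.47 and 0.82) and 7 were called, which argued against that trend as the whole cause; the 4 whose calls ended had smaller folds at like SE, MT-CO2 0.66 to 0.47 (SE 0.13 and 0.14), MT-CO3 0.52 to 0.35 (0.11 and 0.12), MT-ND4 0.65 to 0.53 (0.15 and 0.15) and MT-ND4L 0.51 to 0.14 (0.13 and 0.13). Low complexity of SEPHS1 replicates 1 and 3 would leave SEPHS1 replicate 2 with a low median, but alone it gave 0.54, against 0.73 with all 3. VRTN replicate 3, also of low complexity, had 36.7% of its counts on mitochondrial genes. That was not above both other VRTN libraries (29.2 and 36.9%). Each of these values rests on 1 library, which decides nothing, so low complexity cannot be told apart from the knockdown. Harvest at 72 h cannot be told apart either: DSCC1 siRNA cells, also at 72 h, lay below SEPHS1 siRNA cells by a median of -0.35 with 1 mRNA called, and above the controls by 0.46. With the length and GC trend removed the median of DSCC1 against SEPHS1 siRNA cells was -0.22, with 0 called. An effect of the SEPHS1 knockdown itself stays open, as untested, since no 72 h control is labelled.

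SEPHS1 was lower in SALL4 siRNA cells, at a log2 fold change of -0.99. Carry-over of RNA from SEPHS1 siRNA cells would move the other genes of the SEPHS1 knockdown too. Over 50 genes called between SEPHS1 and DSCC1 siRNA the slope was -0.0934, against 0.307 for SEPHS1 itself. Its SE of 0.0453 takes the genes as independent. The slope argued against carry-over of RNA. It cannot decide on carry-over of the siRNA, since those genes were called at 72 h and the SALL4 libraries were harvested at 48 h. Against replicate 1 or replicate 2 of the controls SEPHS1 was called, with -0.94 the smaller fold, which argued against the difference between control replicates. With the length and GC trend removed it stood at -0.96 and was called, which argued against that trend. A response to the SALL4 knockdown and a direct effect of the SALL4 siRNA pool on the SEPHS1 transcript are hypotheses that stay open, neither of them tested. Carry-over of SEPHS1 siRNA stays open too.

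Other splits of the compared libraries were fitted with those libraries alone. The real split of SALL4 and control libraries called 498 genes and the highest of the other 34 called 47. For VRTN these were 286 and 67, for DSCC1 46 and 14, and for SEPHS1 303 and 6. In each of these 4, 1 of 35 splits, the real one, gave as many genes, the smallest share that 35 splits allow. That argued against a chance split of freely exchanged libraries but cannot exclude it, as the share was not adjusted over the 4 comparisons. These fits also differ from the reported one, in which DSCC1 had 9 called genes. The 4 comparisons used the same controls and are not independent, and free exchange makes no allowance for the structure described above. In 3 comparisons the highest other split followed that structure: for SALL4 and VRTN it put replicate 2 of both controls together with replicate 3 of the knockdown, and for DSCC1 it put replicate 1 of both controls together with DSCC1 replicate 3. For SALL4 against VRTN the real split called 193 and the highest other 0, and for DSCC1 against SEPHS1 37 and 0. Those 10 splits each are too few for a share under 0.05.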

How the results depend on the processing

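Chosen after results were seen were 5 settings: replicate 1 or replicate 2 of the controls alone, the length and GC correction, leaving out mitochondrial genes and their copies, and leaving out SEPHS1 replicates 1 and 3 together. The others were fixed before the data were examined. Counts are of called genes, and the cause of a change was not tested unless stated.

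DESeq2 size factors and upper quartile scaling in edgeR left each count within 1.5 times its value. With no low-count filter the counts were 397 for VRTN, 99 for DSCC1, 516 for SEPHS1, 726 for SALL4 against VRTN and 151 for DSCC1 against SEPHS1. With the strict filter DSCC1 had 2. A 2-fold minimum, which only removes genes, left 226 for SALL4, 78 for VRTN, 0 for DSCC1, 124 for SEPHS1, 229 for SALL4 against VRTN and 33 for DSCC1 against SEPHS1. With only the groups compared, DSCC1 had 46 and SALL4 against VRTN 193.

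Against Luciferase alone the counts were 236 for SALL4, 89 for VRTN, 2 for DSCC1 and 128 for SEPHS1, and against Control alone 280, 95, 2 and 103. Against replicate 1 of the controls SALL4 had 342 and 6 lists, and DSCC1 had 109 and 8 lists. Against replicate 2 of the controls VRTN had 5 lists, DSCC1 4 genes and SEPHS1 137.

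DESeq2 gave 392 for VRTN, 52 for DSCC1, 533 for SEPHS1 and 188 for DSCC1 against SEPHS1. It gave no adjusted p for the DSCC1 transcript in DSCC1 siRNA cells. limma-voom gave 1291 for SALL4, 348 for VRTN, 41 for DSCC1, 158 for SEPHS1, 897 for SALL4 against VRTN and 24 for DSCC1 against SEPHS1. Corrected for length and GC, DSCC1 had 3 genes and 3 lists, and DSCC1 against SEPHS1 had 29 genes. Without SEPHS1 replicates 1 and 3 together the SEPHS1 comparison had 94 and DSCC1 against SEPHS1 had 19. The larger part of the called genes turned from lower to higher for SEPHS1, at 39.3% higher in the report, with limma-voom (61.4%) and the length and GC correction (51.2%). For DSCC1, with all 9 higher, 54 were higher and 55 lower against replicate 1 of the controls.

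The replicate block assumed that equal numbers mark libraries made together, and over 36 same-number pairs of different groups the median correlation of all tested genes was 0.00218, the highest 0.0900. The 2 controls, alike by number at 0.338 over 5526 more abundant genes, gave 0.0795 there. With the block DSCC1 had 15 and DSCC1 against SEPHS1 had 147.

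List counts fell from 15, 8, 5 and 5 for SALL4, VRTN, DSCC1 and SEPHS1 to 3, 1, 0 and 0 with an estimated correlation. fry called 7 for SALL4, 3 for VRTN and 0 for DSCC1, and its count for SEPHS1 stayed within 1.5 times the 5 that camera called.

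The SALL4 transcript in SALL4 siRNA cells, not called at -0.36, passed the threshold in 7 fits. These were the replicate block (-0.38, adjusted p = 0.0365), replicate 2 of the controls (-0.45, 0.0444), DESeq2 (-0.35, 0.00788), limma-voom (-0.38, 0.00563), mitochondrial genes left out (-0.36, 0.0433), and those without Control replicate 1 (-0.44, 0.0292) or SALL4 replicate 3 (-0.42, 0.0218). Over its alternatives the adjusted p ran from 0.00563 to 0.664. The other 3 targets kept their call or lack of one in each fit that gave a value.

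Genes shared by 2 knockdowns, with the first against Luciferase and the second against Control and then the reverse, were 25 and 17 for SALL4 and VRTN, 2 and 1 for SALL4 and DSCC1, 9 and 10 for SALL4 and SEPHS1, 0 and 0 for VRTN and DSCC1, 1 and 2 for VRTN and SEPHS1, and 2 and 2 for DSCC1 and SEPHS1. DESeq2 gave 136, 27, 85, 15, 72 and 33. The strict filter gave 2 for SALL4 and DSCC1 and 2 for DSCC1 and SEPHS1. The replicate block gave 1 for VRTN and DSCC1 and 15 for DSCC1 and SEPHS1. With separate controls each contrast used 2 control libraries and called fewer genes, so those lower counts cannot be put down to the separation alone.

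Leaving out 1 library at a time gave 275 to 924 genes for SALL4, 135 to 271 for VRTN, 2 to 98 for DSCC1, 135 to 472 for SEPHS1, 248 to 879 for SALL4 against VRTN, 22 to 71 for DSCC1 against SEPHS1 and 0 to 1 for Control against Luciferase. Lists ran from 10 to 19, 5 to 8, 2 to 8 and 4 to 8 for the 4 knockdowns. The targets ran from -0.44 to -0.28 for SALL4, -2.83 to -2.68 for VRTN, -2.41 to -2.09 for DSCC1 and -2.99 to -2.60 for SEPHS1. Where a control group kept 1 library, that library was assumed to vary like the others.

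Direction turned in 13 fits, all of genes not called. VRTN in SALL4 siRNA cells, at 0.014, stood at -0.0045 with the replicate block and -0.0072 against replicate 2 of the controls, and ran from -0.038 to 0.072 without 1 library. It was negative without Luciferase replicate 2 (-0.012), Control replicate 1 (-0.034) or SALL4 replicate 1 (-0.038). SALL4 in VRTN siRNA cells, at -0.029, stood at 0.074 against replicate 1 of the controls and 0.028 corrected for length and GC. It ran from -0.10 to 0.055, positive without Control replicate 2 (0.055) or VRTN replicate 2 (0.025). SALL4 in DSCC1 siRNA cells, at -0.057, stood at 0.047 against replicate 1 of the controls and ran from -0.13 to 0.027, positive without Control replicate 2. VRTN in DSCC1 siRNA cells, at 0.058, ran from -0.0044 to 0.11, negative without DSCC1 replicate 3. GBX2 in SEPHS1 siRNA cells, at -3.00, stood at 0.33 against replicate 2 of the controls.

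Over all fits of the named genes 2700 kept their call or lack of one, 345 lost a call, 58 gained one and 13 turned. Single lists kept their result in 366 fits and lost a call in 134. Of the named genes called, 20 of 42 in SALL4, 6 of 26 in VRTN, 2 of 7 in DSCC1, 12 of 23 in SEPHS1, 7 of 10 in SALL4 against VRTN and 1 of 10 in DSCC1 against SEPHS1 kept their call in each fit.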

Other observations

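The comparison of replicate numbers within the controls was chosen only after the result was seen. A fit over 16 libraries called 3 genes between replicate 1 and replicate 2 of the controls, with 661 at an unadjusted p under 0.05. A fit over the 4 control libraries alone called 148, with 1510 at an unadjusted p under 0.05, and had almost no residual freedom.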
